A study of Mus musculus with 12 samples.

How the data were processed

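Gene counts from bulk RNA-seq of total RNA were analysed for the mouse melanoma lines B16 and YUMM1.1, each untreated or given 10 ng/ml recombinant mouse IFNG for 48 h, with 3 libraries per group and 12 in all. Groups and library numbers were taken from the sample labels. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. By the chi-square per degree of freedom of their counts, B16 IFNG 1 and IFNG 2 were at 1.28 to each other and at 18.5 and 18.2 to IFNG 3. The pairs of B16 controls were at 1.59 to 3.42, and those of the deeper YUMM1.1 libraries at 14.7 to 45.4. The deposited count tables hold raw read counts for 55416 Ensembl gene IDs, whole numbers with no normalization. The deposited comparison tables of the authors give a log2 fold change of treated over untreated cells, a test statistic (a score) and an unadjusted p-value per gene and line. These tables were used only for gene symbols and to set their log2 values beside those computed here, and the B16 table repeats 260 gene IDs. The submitters' processing notes name the genome build GRCm38. The aligner, the counting tool, the annotation release and the strand of the libraries are not given in the sources used here.

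Of the gene IDs 52083 had a symbol in GENCODE M21, 366 took one from the deposited tables and 2967 had none. At least 99.8% of the counts of each library were on IDs with an M21 symbol. Some of the IDs without a symbol are of a series that M21 does not hold, and coordinates are those of M21 on GRCm38. Of the genes named in the text 57 overlap another annotated gene, 24 of them a protein-coding gene, so reads in the overlaps could belong to either.

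Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Genes were filtered with filterByExpr at its defaults, libraries were scaled with TMM factors, and edgeR quasi-likelihood F tests with robust dispersions were used. The effect of IFNG was tested within each line on its 6 libraries. The difference of the effects (interaction of line and treatment) and the difference between untreated lines were tested on all 12. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the tested genes of that comparison. The SE is the absolute log2 value over the square root of F. CPM values are counts over library totals. Library totals and the counts they allow set the precision: a group with 0 reads was given a floor of 3 counts over the group, and a group with 1 to 3 reads a ratio with an exact binomial counting interval at 95%.

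The choice of comparisons, thresholds, 27 tested gene lists, 3 lists of other cell types, alternatives and the rule for naming genes was made before the data were examined. The lists cover IFNG receptor, JAK-STAT and IRF factors, negative regulators, MHC class I and II, the immunoproteasome and 20S proteasome, guanylate-binding and immunity-related GTPases, antiviral genes, chemokines, checkpoint genes, ligands of NK cell receptors, pigmentation, dedifferentiation, EMT and matrix, cell cycle, p53 targets, cell death, NF-kB, complement, MAPK output, glycolysis, oxidative phosphorylation, ribosomal proteins, cholesterol, the unfolded protein and integrated stress responses, hypoxia and housekeeping genes, and markers of leukocytes, fibroblasts, and keratinocytes or endothelium. Some genes belong to more than 1 list. Lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01 and adjusted over the 27 lists, and again with an estimated correlation. The markers of other cell types were counted but not tested as lists. Beside the count at the adjustment over all genes, members were counted with an adjustment over the list alone. Another 6 lists were written after the main results were seen and are reported in the closing section, adjusted over those 6 lists.

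Genes were named by a rule. Per line it takes the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM, no overlap between treated and control libraries and a full gene symbol. It adds for each list the 2 called members with the smallest adjusted p and the most abundant member, and a fixed set around the IFNG pathway. For the difference it takes the 8 most positive and 8 most negative called values, and for the untreated lines the pigmentation, dedifferentiation and receptor lists and a few further genes, among them Cdkn2a and Braf. Some genes that the rule takes are left out of the text. Genes named as exceptions in a list, and Atf4, were chosen after their values were seen.

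The alternatives were RLE factors, library totals alone, no filter, a filter of 1 CPM in 3 libraries, DESeq2, limma-voom, a replicate block, an adjusted p below 0.01, all 12 libraries in 1 fit, an estimated correlation for lists, and leaving out each library in turn. Fits of 2 against 2 libraries per line were added after seeing the data. They left out control 3 and IFNG 3 in B16, and control 1 and IFNG 2 in YUMM1.1. Other choices of libraries were possible and were not fitted, so calls lost or gained there may rest on this choice. The pipeline was tested on simulated data with 100 genes changed at each of a log2 of 1 and 2. It recovered 90% and 99% in B16 with 9 false calls of 198, 81% and 97% in YUMM1.1 with 14 of 192, and 60% and 84% for the difference with 11 of 155. Changes were planted only in genes above a minimum mean count, with as many rises as falls. The simulation therefore does not cover genes with few reads or a shift in the scaling. For the difference the changes were planted only in the treated YUMM1.1 libraries. That recovery does not describe differences that come from the shallower B16 libraries. Nothing was left out of the count tables, and Ido1, Nos2 and Ctla4, named in the rule, had too few reads to be tested in either line.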

Results

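RNA-seq read counts of mouse melanoma cells were compared between untreated cultures and cultures given 10 ng/ml recombinant mouse interferon-gamma (IFNG) for 48 h. B16 is a pigmented mouse melanoma line, and YUMM1.1 comes from a mouse model of Braf-mutant melanoma. Each of the 4 groups had 3 libraries. The B16 libraries held 2573805 to 7888257 counts and the YUMM1.1 libraries 19145253 to 24747859. Levels below are CPM (counts scaled to the library total, mean ± SD of 3 libraries), and changes are log2 fold changes of treated over untreated cells with their SE and a Benjamini-Hochberg adjusted p from edgeR. Called means an adjusted p below 0.05. Scaling by library totals in place of TMM factors moved the B16 log2 values by a median of -0.19 and the YUMM1.1 values by -0.08, so changes are relative to the TMM scaling. Mitochondrial transcripts made up 1.95% of the counts of the B16 IFNG 3 library against 1.07% and 1.04% of the other treated B16 libraries, and 0.811% to 1.18% in the B16 controls. They made up 1.104% in YUMM1.1 control 1 against 0.560% and 0.622% in the other controls. Ribosomal protein genes took 4.07% to 4.50% of the counts in B16 controls and 3.02% to 3.37% in treated B16 cells.

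IFNG raised antigen presentation genes and interferon-inducible GTPases in B16, several of them from near 0, and lowered Lgr6, Tenm4 and the stress-response gene Trib3 to a small part of their untreated level. Gbp4, which encodes a guanylate-binding protein, rose from 0.169 ± 0.293 to 962 ± 130.2 CPM (log2 11.93, SE 0.30, adjusted p = 4.44e-09). Tgtp2, Tgtp1 and Iigp1, which encode immunity-related GTPases, rose by log2 11.23, 11.20 and 10.90, and Iigp1 reached 1678 ± 495 CPM. Zbp1, which encodes a nucleic acid sensor, rose from 0.326 ± 0.302 to 749.8 ± 25.3 CPM. All control reads of Gbp4 were in control 1, and the control mean of Zbp1 was 0.190 CPM without control 2. Apol6 had 1 read in the 3 control libraries together and 311 ± 26.6 CPM after treatment, a ratio of 4775 (857 to 188643), the bracket being the 95% counting interval. Gbp10, the immunoproteasome subunit gene Psmb9 and the MHC class II beta chain gene H2-Eb1 had 2 or 3 control reads. Their ratios were 2583 (884 to 12528), 2559 (708 to 21139) and 2433 (673 to 20093). Ifi204 had 0 control reads and 35.7 ± 4.99 CPM in treated cells, at least 185-fold higher against a floor of 3 counts over the group. These intervals and floors cover counting error only.

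Lgr6, which encodes a receptor for R-spondins, fell in B16 from 33.7 ± 1.27 to 0.461 ± 0.131 CPM (log2 -5.96, SE 0.23, adjusted p = 5.31e-08). Tenm4 fell from 15.1 ± 1.68 to 0.228 ± 0.0951 CPM and Odf3l1 from 50.1 ± 0.753 to 1.04 ± 0.610 CPM. Cyp26b1, which encodes an enzyme that breaks down retinoic acid, fell from 14.7 ± 2.11 to 0.495 ± 0.320 CPM (0.325 CPM without IFNG 1). Ache, Rasgrp2, Shisa2, Arap3 and Daam2 fell as well (log2 -4.45, -4.45, -4.37, -4.36 and -4.33). Trib3, which encodes a pseudokinase of the integrated stress response, was the most abundant of the 10 largest falls and went from 432 ± 26.0 to 20.3 ± 4.49 CPM (log2 -4.23, SE 0.16, adjusted p = 4.83e-08). On the GRCm38 assembly as annotated in GENCODE M21, Apol6 is ENSMUSG00000033576, chromosome 15, 77044729 to 77057106, Lgr6 is ENSMUSG00000042793, chromosome 1, 134983301 to 135105276 and Trib3 is ENSMUSG00000032715, chromosome 2, 152337422 to 152344032.

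The IFNG signalling genes of B16 moved in both directions. Irf1, which encodes a transcription factor of the interferon response, rose from 28.9 ± 4.63 to 817 ± 47.4 CPM. Jak2 rose by log2 1.06, the receptor chain gene Ifngr2 fell from 117 ± 7.49 to 55.6 ± 2.37 CPM, and Ifngr1 (log2 -0.44, adjusted p = 0.0696) and Jak1 (log2 0.01) were not called. Ifngr1 was called without IFNG 3 (adjusted p = 0.0121), with library totals (0.0157), with a replicate block (0.0388), in a fit of 2 against 2 libraries added after the data were seen (0.0207) and over the list alone. Of the 11 tested receptor, JAK-STAT and IRF genes 8 rose and 1 fell (median log2 2.62, list adjusted p = 1.61e-16). Among 10 negative regulators 4 rose, led by Socs1 (log2 5.09) and Usp18 (log2 4.97), and Ptpn6 fell (list adjusted p = 0.00564). Among the 4 rises that of Socs2 (adjusted p = 0.0386) was not called by DESeq2 (0.130), by limma-voom (0.0576), with library totals (0.0815), in a fit of all 12 libraries (0.0526) or without any library but IFNG 2 (0.0642 to 0.150). That list had an adjusted p = 0.153 with an estimated correlation between its genes and 0.00281 to 0.0119 under its 10 other alternatives. Wars, which encodes a tryptophanyl-tRNA synthetase, rose from 289 ± 12.1 to 928 ± 41.4 CPM.

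All tested antigen presentation genes of B16 rose. The 17 tested MHC class I and peptide loading genes had a median log2 of 4.35 (list adjusted p = 1.9e-57), and B2m rose from 397 ± 23.1 to 3776 ± 916 CPM. The 8 tested MHC class II genes had a median of 9.33 (list adjusted p = 7.21e-51). Ciita, which encodes the class II transactivator, rose from 0.386 ± 0.389 to 316 ± 41.1 CPM (control mean 0.190 without control 3), and the invariant chain gene Cd74 from 2.23 ± 1.24 to 995 ± 159 CPM. All 5 immunoproteasome and PA28 genes rose (median 5.18, list adjusted p = 3.66e-30), as did 11 of 14 constitutive 20S proteasome genes, by a smaller median of 0.60 (list adjusted p = 0.00129). All 17 guanylate-binding and immunity-related GTPase genes rose (list adjusted p = 4.99e-149, adjusted p = 0.0136 with an estimated correlation), with a median of 10.00, or 8.58 with the genes of 0 to 3 control reads set at their lower bound. All 34 antiviral interferon-stimulated genes rose (median 4.73, at the bound 4.62, list adjusted p = 9.3e-110). Close paralogs such as the H2, Gbp, Tgtp and Apol genes can share reads.

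Cd274, which encodes PD-L1, rose in B16 from 6.88 ± 0.601 to 181 ± 7.54 CPM (log2 4.91, SE 0.12, adjusted p = 4.08e-09). Of 10 checkpoint genes 6 rose, while Nectin2, Ceacam1 and Havcr2 fell (list adjusted p = 7.98e-04). All 4 tested chemokine genes of 14 rose, with Cxcl10 from 13.8 ± 0.732 to 152 ± 10.4 CPM (list adjusted p = 1.49e-04). Of 7 ligands of NK cell receptors 3 rose and Nectin2 fell, and the list (adjusted p = 0.0101) had an adjusted p = 0.0849 with an estimated correlation, against 8.01e-04 to 0.162 under its 10 other alternatives, the highest of them without IFNG 3. In the cell death list 12 of 15 genes rose, or 13 adjusted over the list alone (list adjusted p = 2.98e-13). Complement genes rose in 3 of 4 cases, with C4b from 1.28 ± 0.944 (0.751 without control 3) to 138 ± 21.8 CPM (list adjusted p = 4.15e-09).

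Melanocyte genes of B16 rose more often than they fell. Of 18 pigmentation genes 12 rose and 3 (Pax3, Tyr and Kit) fell (median 0.56, list adjusted p = 1.35e-05). Pax3 was not called when all 12 libraries shared 1 fit (adjusted p = 0.0525). Trpm1 rose from 242 ± 14.5 to 1397 ± 48.7 CPM. Tyrp1, which encodes a melanosomal enzyme, was already at 9359 ± 304 CPM and rose by log2 0.42 (adjusted p = 0.00424). Mitf, the melanocyte lineage factor gene, rose by 0.57 (SE 0.14, adjusted p = 0.00906), and this call was lost without control 1 (adjusted p = 0.0577). Without IFNG 3 the Mitf value was 0.38. With library totals neither Tyrp1 nor Mitf was called (adjusted p = 0.0600 and 0.0526), and over all alternatives at the same threshold the adjusted p ran from 1.77e-07 to 0.0600 for Tyrp1 and 1.29e-07 to 0.0577 for Mitf. Axl rose from 11.5 ± 2.61 to 90.4 ± 13.2 CPM and Nes fell from 317 ± 16.3 to 43.4 ± 3.83 CPM, while the dedifferentiation list (2 up, 1 down of 4) was not called (list adjusted p = 0.858). Among 22 genes of EMT, matrix and adhesion 7 rose and 8 fell, Mcam from 428 ± 15.99 to 63.8 ± 8.79 CPM (list adjusted p = 0.801). Both of these lists had a positive median and a downward test, and the median of the EMT list was 0.09, but -0.10 with library totals.

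Proliferation and stress genes of B16 fell in many cases. Mki67, a proliferation marker gene, fell from 449 ± 68.1 to 176 ± 29.7 CPM, and 20 of 33 cell cycle genes fell (median -0.45, list adjusted p = 0.00198, adjusted p = 0.0868 with an estimated correlation, 1.67e-05 to 0.00263 under the 10 others). Cenpe was called higher (log2 0.37, adjusted p = 0.0451), but not without control 1, control 3, IFNG 1 or IFNG 2 (0.172, 0.0887, 0.104 and 0.0866) or with library totals (0.291) or in a fit of all 12 libraries (0.1797), with an adjusted p of 0.00130 to 0.291 over all alternatives at the same threshold. Cdkn1a, which encodes the CDK inhibitor p21, fell from 248 ± 5.44 to 39.8 ± 4.30 CPM. Of 13 p53 targets and CDK inhibitors 7 fell and Phlda3 rose (list adjusted p = 0.00827, adjusted p = 0.0765 with an estimated correlation, 0.00541 to 0.0187 under the 10 others). Relb fell from 48.5 ± 5.30 to 5.71 ± 1.83 CPM, and 6 of 9 NF-kB genes fell while Sod2 rose (list adjusted p = 0.00160, adjusted p = 0.133 with an estimated correlation, 7.95e-04 to 0.00291 under the 10 others). In the list of the unfolded protein and integrated stress responses 6 genes rose, among them the chaperone gene Hspa5 (log2 0.85), and 6 fell. Asns, which encodes asparagine synthetase, fell from 733 ± 16.5 to 143 ± 10.8 CPM and Atf4 from 964 ± 24.3 to 278 ± 21.3 CPM. That list was called lower (list adjusted p = 0.00243), but had an adjusted p = 0.0532 with an estimated correlation and 9.48e-04 to 0.0911 under its 10 other alternatives, the highest without IFNG 3.

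Cholesterol genes rose in B16. Of 18 genes of cholesterol synthesis and uptake 17 rose (median 1.32, list adjusted p = 5.66e-13), and Srebf2 was not called (log2 0.03, adjusted p = 0.875) except without IFNG 3 (adjusted p = 0.0478). Hsd17b7, which encodes a cholesterol synthesis enzyme, rose from 11.9 ± 1.48 to 159.8 ± 37.2 CPM. Of 30 cytosolic ribosomal protein genes 14 fell (7 without control 1, 6 without control 2, 22 without IFNG 3), or 15 adjusted over the list alone, and 0 were called higher by edgeR with TMM factors or by DESeq2, against 1 by limma-voom and 1 at an unadjusted p below 0.05 (median -0.26, list adjusted p = 0.0169, adjusted p = 0.572 with an estimated correlation, 0.00106 to 0.0331 under the 10 others). Glycolysis genes rose in 9 of 17 cases and Pfkm fell, or 10 and 2 adjusted over the list alone, and the list was not called (list adjusted p = 0.0575), although it was without control 1 (0.0128), without IFNG 3 (4.33e-04), with a CPM filter (0.0488) and with a replicate block (0.0442). Oxidative phosphorylation genes rose in 11 of 21 cases, but in 5 to 7 without a control or IFNG 1, in 17 without IFNG 3 and in 3 with library totals (list adjusted p = 0.148), and that list was called without IFNG 3 (0.00291). Hypoxia genes rose in 3 and fell in 2 of 8 cases, with Ddit4 from 67.4 ± 5.23 to 8.76 ± 0.437 CPM (list adjusted p = 0.351). MAPK output genes rose in 2 and fell in 1 of 11 cases, but with library totals 2 rose and 4 fell (median -0.19, mean 0.19, list adjusted p = 0.858). Of 12 housekeeping genes 3 rose and 2 fell (1 rose without any control, 5 without IFNG 3), or 5 and 2 over the list alone, and with library totals 1 rose and 3 fell (list adjusted p = 0.762). Markers of other cell types were scarce: 1 of 13 leukocyte genes was tested, and Cd68 rose from 2.48 ± 1.93 (1.39 without control 3) to 4.98 ± 1.37 CPM, a call lost without control 1, control 2 or IFNG 1 (adjusted p = 0.137, 0.113 and 0.0783). Of 3 fibroblast genes Pdgfra fell, a call lost without control 1, control 3 or IFNG 1 (adjusted p = 0.0642, 0.0704 and 0.0740) or by DESeq2 (0.0509), and the keratinocyte or endothelial gene tested was not called.

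In all, 4958 of 11240 tested genes were called in B16 by edgeR, 2486 higher and 2472 lower, and 5813 had an unadjusted p below 0.05. Of the calls 889 rises and 821 falls reached an absolute log2 of 1. All 3 treated libraries lay on one side of all 3 controls for 90.5% of called genes. Library totals in place of TMM factors gave 1702 higher and 3872 lower. Of 27 lists tested by camera with a preset correlation 20 were called, 15 up and 5 down, and 13 held with an estimated correlation. The adjusted p of those 13 lists was then 0.0136 to 0.0457, above that of the preset test. The preset camera also called 8 to 12 lists for other splits of the 6 B16 libraries, in which edgeR called 0 genes and 8 to 542 had an unadjusted p below 0.05. Each of these splits sets 2 treated libraries and 1 control against the reverse, so a part of the effect of IFNG stays in it. Adjusted over each list alone the counts were the same as above where no other count is given, apart from the receptor list (2 lower), the EMT list (9 lower) and the hypoxia list (3 lower). Whether the libraries came from separate cultures was not stated, so the p-values measure only the spread between these samples. The counts of IFNG 1 and IFNG 2 had a chi-square per degree of freedom of 1.28 to each other, against 18.5 and 18.2 to IFNG 3, so most of the spread of the treated B16 libraries came from IFNG 3. Without IFNG 3 6368 genes were called.

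**Figure D1:**
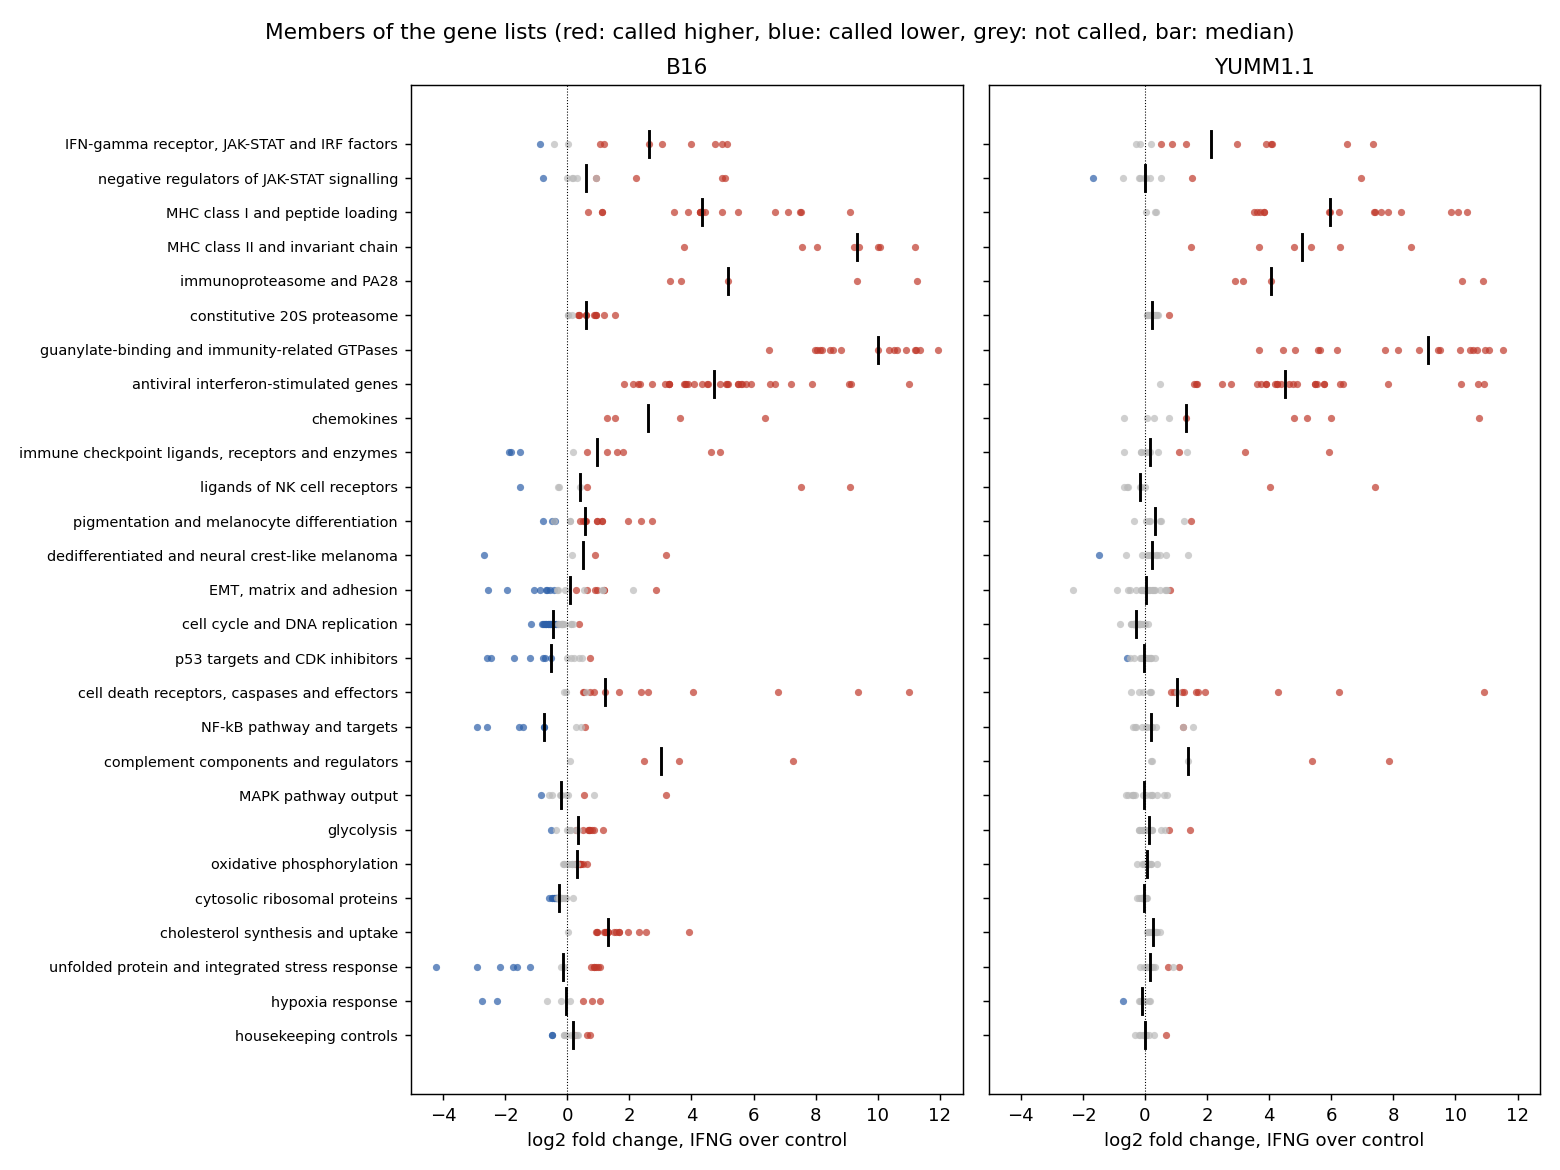
Log2 fold change (IFNG over control) of each tested member of the 27 gene lists in B16 (left) and YUMM1.1 (right), with red for called higher, blue for called lower, grey for not called, and a bar at the median. The guanylate-binding and immunity-related GTPase genes had medians of 10.00 in B16 and 9.13 in YUMM1.1, or 8.58 and 8.49 with genes of 0 to 3 control reads at their lower bound, where MHC class II had 9.32 in B16. The cholesterol genes had medians of 1.32 and 0.27. With library totals the medians of the EMT and housekeeping lists in both lines, and of the negative regulators and oxidative phosphorylation genes in YUMM1.1, changed sign.

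YUMM1.1 cells also raised interferon-inducible GTPases, class I genes and the immunoproteasome, several genes of each from near 0, and their falls were few. Iigp1 rose from 0.720 ± 0.273 to 1331 ± 262 CPM (log2 10.94, SE 0.29, adjusted p = 4.58e-09) and Zbp1 from 0.116 ± 0.0356 to 224 ± 42.6 CPM. Psmb9, the receptor transporter gene Rtp4 and Gbp8 rose by log2 10.88, 10.74 and 10.69. The serine protease inhibitor gene Serpina3f had 1 control read and 107 ± 60.2 CPM after treatment, a ratio of 6544 (1174 to 258504). Batf2 and Apol9a, also with 1 control read, had ratios of 2040.2 (366 to 80616) and 1975 (354 to 78030.1), and Tgtp1 with 3 control reads had 3131 (1071 to 15187). Gbp6 had 0 control reads and 12.02 ± 1.11 CPM in treated cells, at least 245-fold higher. Serpina3f is ENSMUSG00000066363, chromosome 12, 104214544 to 104221129.

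Among genes with a mean of at least 5 CPM the largest called falls in YUMM1.1 were below 4-fold, and the lowest value among all genes tested in that line was a log2 of -2.75. Fmod, which encodes the matrix protein fibromodulin, fell from 18.8 ± 1.77 to 5.43 ± 1.597 CPM (log2 -1.71, SE 0.21, adjusted p = 5.66e-04). Add2 fell from 37.9 ± 6.25 to 11.5 ± 3.73 CPM, the growth factor gene Nrg1 from 21.7 ± 4.74 to 7.34 ± 1.68 CPM and the matrix metalloproteinase gene Mmp3 from 14.9 ± 2.30 to 5.43 ± 1.86 CPM. Fam198b, Zdhhc2, Fnbp1 and Dglucy fell as well (log2 -1.37, -1.30, -1.30 and -1.24). Plxna4 (log2 -1.55, adjusted p = 0.0311) was not called without control 1, control 2, IFNG 2 or IFNG 3 (adjusted p = 0.0858, 0.0884, 0.0964 and 0.0633). Cobl (log2 -1.47, adjusted p = 0.0112) was not called without control 1 or IFNG 2 (adjusted p = 0.0521 and 0.0737). Fmod is ENSMUSG00000041559, chromosome 1, 134037254 to 134048277.

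Irf1 rose in YUMM1.1 from 28.2 ± 2.15 to 443 ± 30.9 CPM. Of 12 receptor, JAK-STAT and IRF genes 9 rose (median 2.14, list adjusted p = 1.12e-43), and Ifngr1, Ifngr2 and Jak1 were not called. Jak2 was called (log2 0.53, adjusted p = 0.0226), but not without control 1, control 3, IFNG 2 or IFNG 3 (adjusted p = 0.0599, 0.0970, 0.0982 and 0.0682). Of 10 negative regulators Usp18 and Socs1 rose and Socs2 fell, Socs1 from 36.4 ± 5.08 to 99.0 ± 14.0 CPM (list adjusted p = 0.258). Wars rose from 165 ± 16.1 to 734 ± 133 CPM.

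Class I and peptide loading genes rose in 16 of 19 cases, or 18 adjusted over the list alone (median 5.95, list adjusted p = 6.69e-190, adjusted p = 0.00960 with an estimated correlation). H2-Q4, a class I gene, rose from 0.615 ± 0.147 to 627 ± 99.9 CPM and B2m from 423 ± 29.7 to 4545 ± 287 CPM. The 6 tested class II genes of 12 rose from low levels (median 5.07, list adjusted p = 1.5e-06, adjusted p = 0.225 with an estimated correlation, 4.49e-12 to 6.27e-06 under the 10 others). Cd74 had 1 control read and 7.99 ± 7.90 CPM after treatment, a ratio of 489 (87.4 to 19343), and Ciita rose from 0.124 ± 0.125 to 5.21 ± 3.999 CPM. Both means rested on IFNG 3 and were 3.43 and 2.91 CPM without it, and the Ciita control mean was 0.0518 CPM without control 1. Among the class II genes H2-DMa (log2 1.48, adjusted p = 0.0273) was not called without control 1, 2 or 3 (adjusted p = 0.0986, 0.0511 and 0.106) or by limma-voom (0.0615), and Cd74 was not called without a filter (0.139). H2-Eb1 (adjusted p = 0.0465) was not called without any library but IFNG 1 (0.0651 to 0.113), by limma-voom (0.0954) or with library totals (0.0508), so that limma-voom called 4 of the 6. All 5 immunoproteasome and PA28 genes rose (median 4.07, list adjusted p = 1.15e-68). Of 14 constitutive 20S genes Psma5 rose, or 3 over the list alone (list adjusted p = 0.0472, adjusted p = 0.725 with an estimated correlation, 0.00548 to 0.295 under the 10 others). That list was not called without control 1, IFNG 1 or IFNG 3 (0.295, 0.155 and 0.211), with a CPM filter (0.0546), with a replicate block (0.0907) or with library totals (0.0738). All 18 guanylate-binding and immunity-related GTPase genes rose (median 9.13, at the bound 8.49, list adjusted p = 7.91e-308, adjusted p = 0.00960 with an estimated correlation). Of 28 antiviral genes 27 rose, or 28 over the list alone (median 4.51, at the bound 4.32, list adjusted p = 4.48e-198, adjusted p = 0.0112 with an estimated correlation).

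Cd274 rose in YUMM1.1 from 0.737 ± 0.0207 to 43.2 ± 10.1 CPM and Cxcl10 from 2.43 ± 0.217 to 147 ± 64.9 CPM. Checkpoint genes rose in 3 of 11 cases, or 5 over the list alone (list adjusted p = 2.6e-05, adjusted p = 0.164 with an estimated correlation, 5.35e-07 to 2.1e-04 under the 10 others). Chemokines rose in 5 of 9 cases, with 1 lower over the list alone (list adjusted p = 1.76e-09, adjusted p = 0.0865 with an estimated correlation, 1.97e-13 to 1.79e-07 under the 10 others). Ligands of NK cell receptors rose in 2 of 8 cases, with a median of -0.15 and a mean of 1.16 (list adjusted p = 1.84e-05, adjusted p = 0.160 with an estimated correlation, 2.24e-07 to 2.75e-04 under the 10 others). Cell death genes rose in 10 of 17 cases, or 11 with 1 lower over the list alone (list adjusted p = 1.02e-22). C4b rose from 0.574 ± 0.295 to 129 ± 62.0 CPM as 1 of 2 complement genes called of 5 (list adjusted p = 7.87e-05, adjusted p = 0.0865 with an estimated correlation, 7.13e-13 to 8.08e-05 under the 10 others).

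The remaining lists of YUMM1.1 held few called genes. Trib3 rose from 13.4 ± 2.64 to 27.4 ± 5.04 CPM (log2 1.11, SE 0.18, adjusted p = 0.00405) and was 1 of 2 stress-response genes called of 14, or of 3 over the list alone (list adjusted p = 0.149), and that list was called without control 3 (0.0205). Glycolysis genes rose in 2 of 17 cases, or 3 over the list alone (list adjusted p = 0.158). Snai2 rose by log2 0.80 and was the EMT gene called of 29, with 2 over the list alone, a median of 0.03 (-0.05 with library totals) and a mean of -0.00337 (list adjusted p = 0.730). Mc1r was the pigmentation gene called of 8, with 2 over the list alone (list adjusted p = 0.251). Its adjusted p was 0.0219, and 0.0684 to 0.0867 without any control or without IFNG 1 or IFNG 2, and 0.0641 with a replicate block. Nrg1 was the dedifferentiation gene called of 13 (list adjusted p = 0.863), and Mitf was not called. Single genes were called in the p53 (16 genes, list adjusted p = 0.444), NF-kB (13 genes, 0.558), hypoxia (8 genes, 0.444) and housekeeping lists (12 genes, 0.965).

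In 5 lists edgeR with TMM factors and its default filter called 0 genes in YUMM1.1. In the cell cycle list it called 1 lower with library totals or a replicate block, 2 in a fit of all 12 libraries and 3 without a filter. Mki67 (log2 -0.79, adjusted p = 0.123) was called lower with a replicate block (0.00305), without a filter (1.58e-06), in the fit of all 12 libraries (0.0426) and by DESeq2 (0.00591). Of the MAPK genes it called 2 lower with library totals, 2 higher and 3 lower without a filter, 1 each way without IFNG 1 and 1 higher in the fit of all 12 libraries, and of the cholesterol genes 1 higher without a filter and in that fit. The oxidative phosphorylation and ribosomal lists had 0 under all these alternatives. Of 33 cell cycle genes 16 were lower at an unadjusted p below 0.05, DESeq2 called 1 lower and limma-voom 0 (median -0.30, list adjusted p = 5.23e-05, adjusted p = 0.668 with an estimated correlation, 7.33e-07 to 0.00520 under the 10 others). Of 18 cholesterol genes 5 were higher at an unadjusted p below 0.05, DESeq2 called 1 higher and limma-voom 0. That list (median 0.27, list adjusted p = 0.0432) had an adjusted p = 0.709 with an estimated correlation and 0.00102 to 0.300 under its 10 other alternatives, and was not called without control 2, IFNG 1, IFNG 2 or IFNG 3 (0.300, 0.0997, 0.0746 and 0.0959), with a CPM filter (0.0536), with a replicate block (0.0576) or with library totals (0.0634). Of 14 MAPK output genes 2 were higher and 5 lower at an unadjusted p below 0.05, DESeq2 called 1 each way and limma-voom 0 (list adjusted p = 0.583). Adjusted over the list alone edgeR called 1 higher and 2 lower. Of 21 oxidative phosphorylation genes 1 was higher and 1 lower at an unadjusted p below 0.05, and of 30 ribosomal protein genes 0 were, with 0 called by DESeq2 or limma-voom in either list (list adjusted p = 0.863 and 0.444). The ribosomal list was called lower without control 1 (0.00419). Of 3 leukocyte, 3 fibroblast and 1 keratinocyte or endothelial genes tested 0 were called by the 3 tools, and 2 fibroblast genes were lower at an unadjusted p below 0.05 and over the list alone.

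In YUMM1.1 591 of 12970 tested genes were called by edgeR, 484 higher and 107 lower, and 1948 had an unadjusted p below 0.05. An absolute log2 of 1 was reached by 327 rises and 44 falls. All called genes had the 3 treated libraries on one side of the 3 controls. The count of lower genes was 38 without IFNG 2, 64 without control 2 and 68 without control 3, and library totals gave 425 higher and 178 lower. Of 27 lists 14 were called, 13 up and 1 down, and 6 held with an estimated correlation. The adjusted p of those 6 lists was then 0.00960 to 0.0299, above that of the preset test. Other splits of the 6 libraries called 1 to 13 lists where edgeR called 0 or 1 genes and 51 to 1711 had an unadjusted p below 0.05. A fit of 2 against 2 libraries, added after the data were seen, called neither Trib3, Nrg1, Mmp3, Fam198b and Socs2 (adjusted p = 0.115, 0.0555, 0.0633, 0.0758 and 0.103) nor the genes above whose call rested on 1 library.

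The genes raised by IFNG overlapped between the lines. Of 10689 genes tested in both, 322 were called higher in both where independence predicts 86.5, and 32 lower in both where it predicts 13.9. Another 13 were higher in B16 and lower in YUMM1.1 (14.1 predicted), and 26 the reverse (85.4 predicted). With an absolute log2 of at least 1 in both, 214 were higher in both, 3 lower in both and 4 opposite. The log2 values had a Pearson correlation of 0.697 and a Spearman correlation of 0.283, and the Pearson correlation was 0.159 without the 322 shared rises.

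**Figure D2:**
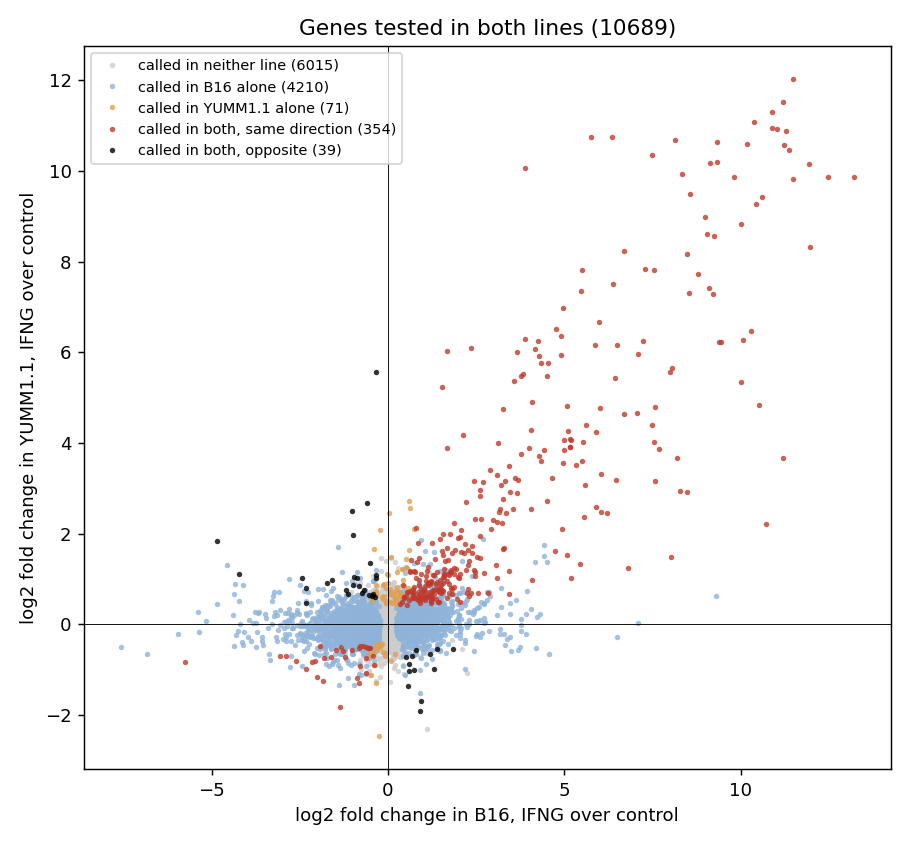
Log2 fold change (IFNG over control) in YUMM1.1 against B16 for the 10689 genes tested in both lines, one point per gene, coloured by its calls at an adjusted p below 0.05. The 322 genes called higher in both lines lie in the upper right, and the lower left holds 32 genes called lower in both.

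The effect of IFNG differed between the lines for most cholesterol and stress-response genes and for some antigen presentation genes, as tested by the interaction of line and treatment, although no list held with an estimated correlation. Of 18 class I genes 5 had a higher and 7 a lower effect in YUMM1.1, and that list was not called (list adjusted p = 0.489). A positive difference means a higher log2 change in YUMM1.1. H2-Q4 rose in both lines but more in YUMM1.1, with a difference of 6.19 (SE 0.32, adjusted p = 6.47e-09), and in B16 it went from 8.81 ± 2.01 to 119 ± 20.5 CPM. H2-Q4 is ENSMUSG00000035929, chromosome 17, 35379617 to 35385290. Cfap70 had a difference of 7.37, from 2.66 CPM to 0 reads in B16 and from 8.18 to 4.91 CPM in YUMM1.1, and Apobr, Akr1b7, Cyp26b1, Enpp2 and Lgr6 had 6.75, 6.27, 5.94, 5.83 and 5.80. Chst3 (difference 5.77, adjusted p = 0.0470) was not called without any single B16 library, YUMM1.1 control 3 or any YUMM1.1 IFNG library (adjusted p = 0.0516 to 0.125), or with a replicate block (0.0971). The most negative differences were those of Fcgr4, Cdh6, Ifi204 and H2-Eb1, at -10.76, -9.82, -9.66 and -7.67. Fcgr4 (adjusted p = 0.0332) was not called without B16 control 1 (0.0574) or YUMM1.1 control 2 (0.9999). H2-Eb1 (adjusted p = 0.0193) was not called without B16 IFNG 3, YUMM1.1 control 2 or YUMM1.1 control 3 (0.0632, 0.0603 and 0.122), or without a filter (0.142). Smad9, Rapgef5, Slco2a1 and H2-DMa had differences of -7.15, -7.10, -6.82 and -6.56. Several of these genes were at 0 or a few reads in a group, where a fitted difference depends on the prior count.

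Trib3 had a difference of 5.36 (SE 0.25, adjusted p = 2.24e-09), Asns of 2.31 and Atf4 of 1.70. Hsd17b7 had -3.67 (SE 0.25, adjusted p = 8.73e-08). By log2 change Irf1 and Socs1 rose less in YUMM1.1 (-0.91 and -3.55), whereas Cd274 and Cxcl10 rose more (1.05 and 2.37), from lower untreated levels. In CPM, Cd274 of treated cells stayed lower in YUMM1.1 than in B16, and Cxcl10 was similar in both. The difference of Cd274 (adjusted p = 0.0206) was not called without B16 control 2 (0.0665) or by limma-voom (0.106), and it was not called in the fit of 8 libraries added later (0.133). B2m (0.08, adjusted p = 0.837), Mki67 (0.39, 0.428), Mitf (-0.04, 0.974), Cd74 (-0.86, 1.000) and Ciita (-4.75, 0.111) had no called difference. That of Ciita was called by DESeq2 (0.00166) and limma-voom (0.0168), with a replicate block (0.0185) and without YUMM1.1 IFNG 3 (0.00115). Cd74 and Ciita were near 0 in untreated YUMM1.1 cells, so their log2 changes there are imprecise. Their treated levels did differ: Cd74 was at 812 to 1088 CPM in B16 and 3.19 to 17.1 CPM in YUMM1.1. Ciita was at 269 to 340 and 2.78 to 9.83 CPM. Of 18 cholesterol genes 16 had a lower effect in YUMM1.1 (list adjusted p = 6.77e-17, adjusted p = 0.0730 with an estimated correlation). Of 14 stress-response genes 6 had a higher and 4 a lower effect (list adjusted p = 7.44e-07, adjusted p = 0.107 with an estimated correlation). Of 13 NF-kB genes 7 had a higher and 1 a lower effect (list adjusted p = 4.93e-07, adjusted p = 0.0730 with an estimated correlation).

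Of 13603 genes tested 2510 had a called difference, 1353 with the higher effect in YUMM1.1 and 1157 with the lower, and 4224 had an unadjusted p below 0.05. With library totals the split was 1727 to 886, with RLE factors 1224 to 1326 and by DESeq2 1305 to 1530, so which direction had more genes depended on the setting. Of 27 lists 10 were called, and 0 held with an estimated correlation, where 0.0730 was the lowest adjusted p.

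**Figure D3:**
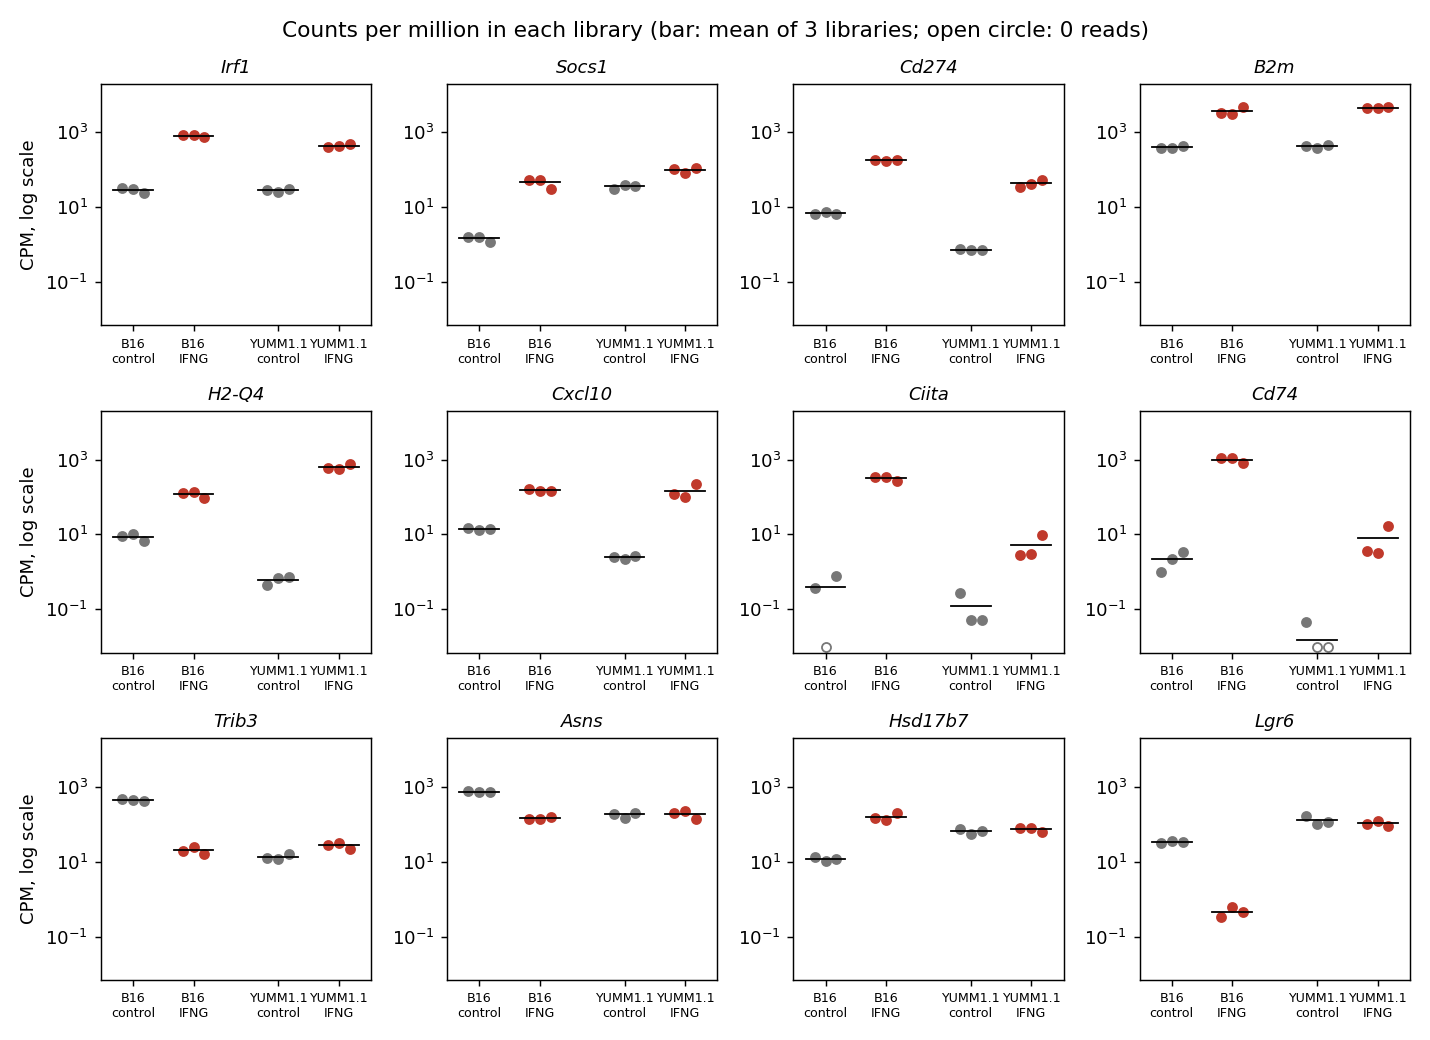
CPM on a log scale of 12 genes in each of the 12 libraries, with a bar at the mean of each group of 3 and open circles at the lower edge for libraries with 0 reads. Trib3 fell from 432 to 20.3 CPM in B16 and rose from 13.4 to 27.4 CPM in YUMM1.1, while B2m ended at 3776 and 4545 CPM.

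Untreated YUMM1.1 cells had little melanocyte differentiation RNA relative to untreated B16, and higher levels of 10 of 12 dedifferentiation genes. Tyrp1 was at 9359 ± 304 CPM in B16 and had 0 reads in YUMM1.1, Dct at 9498 ± 159 against 0.0149 ± 0.0258 CPM, Pmel at 5784 ± 301 against 2.10 ± 0.279 CPM and Mitf at 536 ± 22.1 against 1.66 ± 0.147 CPM (log2 -8.11, adjusted p = 1.27e-14). Ngfr, which encodes a neurotrophin receptor, was at 0.474 ± 0.139 CPM in B16 and 2945 ± 97.9 CPM in YUMM1.1, and Axl at 11.5 ± 2.61 and 1247 ± 63.4 CPM (log2 6.996). Sox10 was not called (log2 -0.23, adjusted p = 0.201), except without B16 IFNG 3 (0.0458). Ifngr1 was higher in YUMM1.1 (log2 2.20) and Ifngr2 lower (log2 -1.53). Cdkn2a had 0 reads in B16 and 6.33 ± 1.02 CPM in YUMM1.1, and Braf was at 60.03 ± 7.49 and 23.3 ± 3.37 CPM. Of 18 pigmentation genes 17 were lower in YUMM1.1 (list adjusted p = 9.13e-65). The dedifferentiation list (10 of 12 genes higher) was called higher (list adjusted p = 1.11e-10) with an adjusted p = 0.0605 with an estimated correlation. The EMT, MAPK, cholesterol, p53 and cell death lists were called higher and the stress-response list lower, with adjusted p = 0.0605 to 0.486 with an estimated correlation. Between untreated lines 9267 of 13603 genes were called, 4721 higher and 4546 lower in YUMM1.1, and 9611 had an unadjusted p below 0.05. With library totals 3802 were higher and 5595 lower. Depth differed with the line, and whether the lines were prepared or sequenced apart is not given in the sources used here, so the baseline difference cannot be assigned to the line alone.

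The authors' deposited table for B16 gave log2 fold changes with a Pearson correlation of 0.999 to those above over 11240 genes and a median difference of 0.02. The authors' deposited table for YUMM1.1 gave a correlation of 1.00 over 12970 genes, and a log2 value of opposite sign for 16 genes against 255 in B16.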

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

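The tests of a larger spread between YUMM1.1 replicates and of fewer reads in the YUMM1.1 libraries were chosen after the counts of called genes were seen, as were the names of genes outside the rule.

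The results listed here were picked out because the effect of IFNG differed between the lines by the interaction test. In all 2510 of 13603 genes had a called difference. Of the 100 splits of the libraries within each line, 2 called as many genes, the real split with 2510 and another with 3097. The share is below 0.05, but the splits were not alike: the 9 other splits that kept the real B16 groups called 1882 to 3097 genes, and the 90 that regrouped B16 called 0 to 3. The count therefore rests on the B16 response more than on the grouping of the YUMM1.1 libraries. Regrouping mixes treated and untreated B16 libraries, which adds any real effect to the spread and lowers the count by design. The share therefore decides nothing.

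Among genes that fell in B16 and did not fall more in YUMM1.1, the difference of the log2 effects (YUMM1.1 minus B16) was 7.37 for Cfap70, 6.75 for Apobr, 6.27 for Akr1b7, 5.94 for Cyp26b1, 5.83 for Enpp2, 5.80 for Lgr6, 5.77 for Rasgrp2, 5.69 for Odf3l1, 5.46 for Ache, 5.36 for Trib3, 5.26 for Daam2, 5.09 for Shisa2, 5.02 for Tenm4, 3.94 for Arap3, 3.17 for Relb, 3.05 for Mcam, 2.95 for Ddit4, 2.91 for Nes, 2.42 for Cdkn1a, 2.31 for Asns, 1.70 for Atf4, 1.39 for Nectin2, 0.75 for Pfkm and 0.61 for Ifngr2. Among genes called higher in both lines it was 6.19 for H2-Q4, 4.93 for Rtp4, 2.37 for Cxcl10, 1.05 for Cd274, -0.51 for Jak2, -0.76 for Psma5, -0.91 for Irf1, -3.55 for Socs1, -3.86 for Apol6, -6.56 for H2-DMa, -7.67 for H2-Eb1 and -9.66 for Ifi204. Among genes called higher in B16 and not in YUMM1.1 it was -0.50 for Sod2, -0.60 for Hspa5, -0.61 for Phlda3, -1.93 for Fam198b, -2.59 for Socs2, -3.26 for Axl, -3.67 for Hsd17b7, -4.90 for Trpm1, -6.82 for Slco2a1, -7.10 for Rapgef5, -7.15 for Smad9, -9.82 for Cdh6 and -10.76 for Fcgr4. In YUMM1.1 Trpm1 had 2 control reads, Fcgr4 had 1 control and 0 treated reads, and Smad9 had 11 and 0. For these genes a lack of response in YUMM1.1 cannot be told from a lack of expression. Among the remaining genes, not called or not tested in B16, it was 5.77 for Chst3, 1.41 for Mc1r and -0.95 for Zdhhc2. Some of these calls depended on single libraries. Those of Jak2 and Phlda3 were lost without any of 9 of the 12 libraries (adjusted p = 0.0568 to 0.119 and 0.0697 to 0.110), and that of Zdhhc2 without any of 9 (0.0547 to 0.210). Jak2 was still called without B16 IFNG 2, YUMM1.1 control 1 or YUMM1.1 IFNG 3. Phlda3 was still called without B16 IFNG 3, YUMM1.1 control 1 or YUMM1.1 IFNG 3. Zdhhc2 was still called without B16 IFNG 1, YUMM1.1 control 3 or YUMM1.1 IFNG 3. The call of Sod2 was lost without B16 control 1, B16 control 2, B16 IFNG 2 or YUMM1.1 IFNG 1 (0.0697, 0.0658, 0.0533 and 0.0518). The call of Trpm1 was lost without YUMM1.1 control 1, control 2, IFNG 1 or IFNG 2 (0.1004, 0.113, 0.05002 and 0.0565). The call of Ifngr2 was lost without B16 control 1 or B16 control 3 (0.0574 and 0.0561), and that of Cd274 without B16 control 2 (0.0665). With library totals the calls of Jak2, Phlda3, Zdhhc2 and Sod2 were lost (0.0902, 0.0762, 0.0746 and 0.0584), with a replicate block those of Jak2 and Zdhhc2 (0.0564 and 0.104), by limma-voom those of Phlda3 and Zdhhc2 (0.0557 and 0.105), and without a filter those of Jak2 and Sod2 (0.142 and 0.154). Within B16 the call of Enpp2 was lost without control 2, IFNG 1 or IFNG 2 (0.0622, 0.0511 and 0.0591) and in a fit of all 12 libraries (0.250). In that fit its B16 value was a log2 of -0.37 and its YUMM1.1 value 5.46, from 2 to 122 reads. The difference of Enpp2 therefore came mainly from YUMM1.1, where the treated mean was 1.72 CPM, or 1.02 without IFNG 3. Within B16 the call of Fam198b was lost without any control (0.0716 to 0.168) and that of Socs2 without any library but IFNG 2 (0.0642 to 0.150), and Zdhhc2 was called without IFNG 3 (0.00473). Within YUMM1.1 the call of H2-Eb1 was lost without any library but IFNG 1 (0.0651 to 0.113). For Chst3, Fcgr4 and H2-Eb1 the libraries are named with the comparison above, with adjusted p values up to 0.125, 0.9999 and 0.122.

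Of the 27 gene lists 10 were called by the interaction test with a preset correlation. The list adjusted p was 6.77e-17 for cholesterol (lower effect in YUMM1.1), 4.93e-07 for NF-kB (higher), 7.44e-07 for the stress responses (higher), 4.29e-04 for MHC class II (lower) and 9.8e-04 for the guanylate-binding and immunity-related GTPases (lower). It was 0.00727 for p53 targets (higher), 0.00951 for the 20S proteasome (lower), 0.0111 for cell death (lower), 0.0143 for negative regulators of JAK-STAT signalling (lower) and 0.0445 for ribosomal proteins (higher). With an estimated correlation the adjusted p was 0.0730 to 0.834 and 0 of the 10 were called, and with RLE factors the ribosomal list was not called (0.0694).

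Fewer genes were called in YUMM1.1 (591) than in B16 (4958), although the YUMM1.1 libraries were deeper. The coefficient of biological variation was 0.146 in YUMM1.1 and 0.121 in B16, but a larger spread as the whole cause was argued against by the sizes of the effects. Among 8175 genes at 10 CPM or more in both lines, 3 had a log2 of -1 or less in YUMM1.1 against 336 in B16, called or not, a ratio of 0.00893, and 158 against 486 had a log2 of 1 or more. Fewer reads were argued against as well, because the lowest YUMM1.1 total was 2.43 times the highest B16 total. A thinning of the YUMM1.1 counts, planned for this question, could only lower their count of called genes and is not used here. A weaker response of YUMM1.1 beyond the shared rises may explain the difference, but whether the lines were cultured, prepared or sequenced apart is not given in the sources used here, and a share of the larger spread stays possible.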

How the results depend on the processing

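The fits of 2 against 2 libraries per line were chosen after seeing the data, and the other alternatives were planned. No list or named gene was called in the opposite direction under an alternative. Which direction had more genes did turn: for the difference more were lower with RLE factors (1224 higher, 1326 lower) and by DESeq2 (1305 and 1530). In B16, with nearly as many falls as rises, more were lower with library totals (1702 and 3872), without a filter (2772 and 2787), by limma-voom (2466 and 2515), with a replicate block (2876 and 2889), in the fit of all 12 libraries (2435 and 2550) and without control 1, 2 or 3 (1861 and 1869, 1823 and 1905, 2002 and 2123). RLE factors and a CPM filter kept all counts of called genes within 1.5 times. With library totals alone 3872 genes were lower in B16 and 178 in YUMM1.1, because all treated libraries then shift down together. At an adjusted p below 0.01 B16 had 3295 calls (1580 lower), YUMM1.1 357 (34 lower) and the difference 1355 (752 higher, 603 lower). Without a filter YUMM1.1 had 1055 calls, 781 higher and 274 lower. DESeq2 gave 197 lower genes in YUMM1.1 and 53 genes lower in both lines, and the 2 against 2 fit gave 315 calls in YUMM1.1, 297 higher and 18 lower. In these cases the cause was not tested. At an absolute log2 of at least 1 the overlaps were 214 higher in both, 3 lower in both and 4 opposite, since fewer genes qualify. With an estimated correlation 13 lists were called in B16 and 6 in YUMM1.1. DESeq2 called 4473 genes in B16 and 2835 for the difference, limma-voom 4981 and 2485.

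Leaving out 1 library at a time gave 3728 to 6368 calls in B16 (1823 to 3188 higher, 1869 to 3180 lower), 426 to 583 in YUMM1.1 (358 to 482 higher, 38 to 101 lower), 1784 to 2616 for the difference (954 to 1402 higher, 807 to 1214 lower) and 8512 to 9978 between untreated lines (4333 to 5186 higher, 4019 to 4792 lower). It gave 20 to 21 lists in B16 and 12 to 15 in YUMM1.1. Whether the library numbers pair treated with control samples cannot be told in B16. Deviations of the same number correlated there at 0.364, -0.0138 and 0.374, but control 1 correlated with IFNG 2 at 0.382. In YUMM1.1 the same numbers correlated at -0.0495, -0.556 and 0.0776, which gave no sign of pairing by number. There control 1 correlated with IFNG 2 at 0.606 and control 2 with IFNG 3 at 0.378. The replicate block uses the library numbers and cannot test a pairing across them. With a replicate block the counts were 5765 in B16, 560 in YUMM1.1, 2338 for the difference and 9148 between untreated lines. Depth limits the low end: a floor of 3 counts was 0.38 to 1.17 CPM in a B16 library and 0.121 to 0.157 CPM in a YUMM1.1 library, so large ratios of genes near 0 reads are imprecise in B16 above all.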

Other observations

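The gene lists in this part were written after the main results were seen, and so were the tests of nutrient stress, of B16 RNA and of leukocytes. The tests of single libraries, scaling and other splits were planned. List p-values here were adjusted over these 6 lists of a line only. Adjusted together with the 27 planned lists and with an estimated correlation, the ATF4 and IFI200 lists stayed called in B16 (adjusted p = 0.0371 and 0.0484) and the lysosomal list did not (0.0512). The lists hold genes whose changes had already been seen, such as Trib3, Asns and Ifi204. Adjustment does not correct for that choice, so these p-values describe the lists and are not independent support.

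IFNG lowered the RNA of amino acid response genes and raised that of lysosomal genes in B16. Of 28 targets of ATF4 or of the amino acid response 27 fell (median log2 -1.71, list adjusted p = 1.86e-28, adjusted p = 0.0497 with an estimated correlation), and Slc3a2 was not called except with library totals (adjusted p = 0.00866) and in the fit of 2 against 2 libraries (0.0362). Of 18 lysosomal genes 17 rose (median 0.88, list adjusted p = 1.38e-06, adjusted p = 0.0497 with an estimated correlation), and 1 was not called. All 6 tested genes of the IFI200 family and inflammasome sensors rose (median 8.38, list adjusted p = 3.32e-11, adjusted p = 0.0497 with an estimated correlation). In YUMM1.1 3 of 29 ATF4 targets rose and 26 were not called (list adjusted p = 0.209). Of 18 lysosomal genes 3 rose, or 5 over the list alone (list adjusted p = 0.00306, adjusted p = 0.217 with an estimated correlation). Of 5 IFI200 genes 4 rose (list adjusted p = 2.12e-04, adjusted p = 0.217 with an estimated correlation).

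Of the Schlafen genes 2 of 3 rose and 1 fell in B16 (list adjusted p = 0.0943), and 3 of 4 rose in YUMM1.1 (list adjusted p = 1.76e-05, adjusted p = 0.0817 with an estimated correlation). Fatty acid synthesis genes rose in 7 and fell in 2 of 10 cases in B16 (list adjusted p = 0.174). In YUMM1.1 edgeR and limma-voom called 0 of 11, DESeq2 called 1 higher, and 2 were higher at an unadjusted p below 0.05 (list adjusted p = 0.323). Wnt feedback targets rose in 2 and fell in 1 of 4 cases in B16 (list adjusted p = 0.821), and fell in 2 of 7 cases in YUMM1.1, or 3 over the list alone (list adjusted p = 0.0615).

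The fall of the ATF4 targets in B16 did not rest on a single library, because the highest of the 6 leave-one-out medians was -1.61 and the lowest -1.83. It did not rest on the scaling either, with medians of -1.69 with RLE factors and -1.91 with library totals. An amino acid or nutrient stress of the untreated B16 cultures that treatment relieved could also lower these genes. Untreated B16 cells had higher levels of them than untreated YUMM1.1 cells (median YUMM1.1 minus B16 -1.33), which such a stress predicts, but a difference between the lines predicts it as well, so the explanations cannot be told apart. No medium or cell density record was analysed here.

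MHC class II reads appeared in treated YUMM1.1 libraries, with Cd74 at 3.66, 3.19 and 17.1 CPM and Ciita at 2.78, 3.03 and 9.83 CPM, so that the means rest on IFNG 3 and are 3.43 and 2.91 CPM without it. RNA of treated B16 cells in these libraries was argued against, because Tyrp1, Dct and Pmel together stood at 2.86 CPM where that source would need 246 (ratio 0.0116). Leukocytes cannot be told apart from the YUMM1.1 cells as the source. Of 5 leukocyte genes 3 had 0 reads in every YUMM1.1 library, and all 5 together stood at 2.14 CPM in treated and 2.28 CPM in untreated cells (ratio 0.939). Leukocytes present alike in both and induced by IFNG would give such a ratio too, and 1 of the 5 was highest in IFNG 3, the library with the most Cd74 (2.89 CPM), although it was at 2.30 CPM in an untreated library and the other gene with reads was lowest in IFNG 3 (0.213 CPM). Whether all cells or a few carried them was not tested.

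Other splits of the libraries into groups of the same size were counted for each comparison. For the genes called in B16 1 of 10 splits gave a count as large, the real split with 4958, and the highest other had 0 by edgeR, with at most 542 genes at an unadjusted p below 0.05. For YUMM1.1 it was 1 of 10 with 591 and the highest other had 1, with up to 1711 genes at an unadjusted p below 0.05 where the real split had 1948. For the untreated lines it was 1 of 10 with 9267 and the highest other had 0 by edgeR, with at most 389 at an unadjusted p below 0.05. For the gene lists called it was 1 of 10 in B16, with 20 and a highest other of 12, and 1 of 10 in YUMM1.1, with 14 and a highest other of 13. In these 5 cases the splits are too few for a share under 0.05. Every other split also mixes the real groups, so any real difference adds to its spread within groups. Low counts of called genes in the other splits follow from that mixing, and no conclusion is drawn from them.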
